A study of Homo sapiens with 6 samples.

How the data were processed

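The series holds 6 RNA-seq libraries of MCF7 cells, 3 from stable cells with the empty lentiviral vector and 3 from stable cells with SMYD3 cDNA, selected with puromycin. Groups and replicate numbers were taken from the sample titles. The design text names stable cells, while the extraction protocol in the labels also uses the word tumors, so the growth conditions of the cells at harvest are not settled by the labels.

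Messenger RNA was captured by poly(A) selection and made into libraries with a strand-specific kit, per the labels' protocols. The deposited values are whole-number read counts per gene symbol, 1 column per library, in 1 table of the whole series, and 0 columns of that table belonged to no sample. The submitters' processing notes name bcl2fastq 2.17, STAR 2.6.0c, featureCounts and Subread 1.6.2 and the genome build hg19. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Without the strand setting, reads of overlapping and antisense genes cannot be told apart, and near-identical genes (HLA, AKR1C, keratin and ribosomal protein genes with their pseudogenes) are uncertain. Longer transcripts yield more reads than short ones at equal abundance, so CPM values compare a gene between libraries and not genes with each other.

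The table held 26364 genes, of which 4871 had 0 counts in every library. Library totals ranged from 29066609 to 41442143 counts. A count of 0 allows up to 3 counts of a total; intervals and floors cover counting error only, since reads were not marked by molecule. Genes passing edgeR's filterByExpr with its defaults (minimum count 10, minimum total 15) entered the test, 15226 in all. Counts were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit, glmQLFTest, two-sided, intercept and group) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. SE was the absolute log2 fold change divided by the root of the quasi-likelihood F. CPM means and SD are TMM-scaled. For genes with 0 counts in a group the fold was set against 3 counts over the group, and for those with 1 to 3 counts the ratio carries an exact binomial 95% interval.

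The 31 gene lists were written before the data were examined, as were the design, the rule for named genes and most alternatives. A list needed 5 tested members, and 30 were tested with cameraPR in limma 3.58.1 on the signed root of F at a preset correlation of 0.01; the mitochondrially encoded list was not tested because 0 of its 13 genes were in the table. SMYD3 was left out of the lists. The named genes were SMYD3, 11 key genes and up to 4 members of each list with the smallest p. To these came the 8 genes with the highest and the 8 with the lowest log2 fold change, SMYD3 left out. They were taken from characterised genes past the threshold with a mean log2 CPM of at least 1 and groups that did not overlap. ERBB2, the genes named only as its neighbours and the genes at the ends of other stretches fall outside this rule. So do LDHB, TRIM22, ANKRD30A, COL1A2 and the genes named in the other observations apart from SMYD3 and BTG2. All of these were chosen after their values were seen.

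The gene scripts were tested on simulated counts for this comparison (15075 genes in the step). They recovered 67.3% of genes changed 1.25-fold, 87.8% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, and 2.90% of calls were false. In the simulation 49 or 50 genes were changed at each fold and 30 more were lowered 2-fold. In the data 61.6% of tested genes were called, so these shares were not measured with as many changed genes as the data hold.

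Alternatives were RLE, upper-quartile and no composition factors, no filter on low counts, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, a threshold of 0.01, a log2 fold change of at least 1, and for lists camera with an estimated correlation and fry. Added after seeing the data were offsets for GC content and transcript length (loess span 0.5, longest GENCODE transcript per symbol, 96.9% of tested genes matched), a fit without 111 genes, namely the 70 tested genes between the ends of the ERBB2 stretch (those under a log2 CPM of 1, which the scan of 60 left out, included) and the 43 near-absent genes, of which 2 were in both, and further list settings. Gene order came from a RefSeq table of GRCh38.p14, matched by symbol for 97.9% of tested genes; it is not the build of the counts and served only to say which genes are neighbours. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.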

Results

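Poly(A)-selected RNA of MCF7, an oestrogen receptor-positive luminal breast cancer cell line, was sequenced from stable cells carrying an empty lentiviral vector (control) or a vector with the cDNA of SMYD3, a lysine methyltransferase of the SET and MYND domain family. The 2 groups held 3 libraries each. Control replicates 1, 2 and 3 held 41442143, 30609974 and 29066609 gene counts, and SMYD3 replicates 1, 2 and 3 held 35259043, 37652165 and 29356815. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.79 to 7.72 within groups and 82.6 to 118 between them, so each library was counted once. The labels call the replicates biological without saying whether they came from separate infections, so the p-values measure the spread between libraries of a line and carry over to other infections only if that spread does. The comparison asked which transcripts differed between cells with added SMYD3 and cells with the empty vector.

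SMYD3 mRNA stood at 12.8 ± 0.738 CPM (SD, n = 3) in control cells and at 2142 ± 46.4 CPM (SD, n = 3) in SMYD3 cells. The log2 fold change was 7.40 (SE 0.06), and all 3 SMYD3 libraries lay above all 3 control libraries. The adjusted p was 3.36e-26 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Reads of the introduced cDNA and of the endogenous gene were counted together. SMYD2, a related methyltransferase, rose by a log2 fold change of 0.48 (SE 0.07).

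The highest fold changes were ranked among characterised genes other than SMYD3 with a mean log2 CPM of at least 1 and groups that did not overlap. The first 8 included SCGB2A2, which encodes the secreted breast protein mammaglobin, and TCN1, which encodes a vitamin B12-binding protein. SCGB2A2 had 0 counts in the 3 control libraries together and 924 in the SMYD3 libraries, at least 312-fold higher against a floor of 3 counts over the group. STAC2 likewise went from 0 to 561 counts, at least 190-fold higher. NLRP2 and SOX11, a developmental transcription factor, each had 2 counts in control cells, giving ratios of 469 (95% counting interval 130 to 3880) and 304 (83.7 to 2512). TCN1 rose from 0.202 ± 0.0924 to 81.2 ± 12.7 CPM (SD, n = 3). GPX1, a glutathione peroxidase, rose by a log2 fold change of 7.10 (SE 0.25), the aldehyde dehydrogenase gene ALDH2 by 6.04 (SE 0.16) and the iron exporter gene SLC40A1 by 5.42 (SE 0.21).

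The 8 with the lowest fold change by the same limits were CTGF, IFI44L, NR4A1, EGR2, IFI44, XAF1, UBA7 and IFIT3. CTGF, which encodes a matricellular growth factor, went from 30.3 ± 0.967 to 0.215 ± 0.176 CPM (SD, n = 3), a log2 fold change of -7.10 (SE 0.17). The interferon-stimulated genes IFI44L, IFI44, XAF1 and IFIT3 changed by -5.70, -4.96, -4.67 and -4.48 on the log2 scale, and UBA7, the activating enzyme for ISG15 conjugation, by -4.53. The immediate early transcription factor genes NR4A1 and EGR2 changed by -5.10 (SE 0.07) and -5.03 (SE 0.19).

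Over all genes, 4659 were higher and 4713 lower in SMYD3 cells at an adjusted p under 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), of 15226 tested. Of these, 380 higher and 774 lower genes differed at least 2-fold, and 156 and 176 at least 4-fold. The groups did not overlap in 65.2% of tested genes, against 10% by chance for 3 libraries against 3. The common biological coefficient of variation was 4.35%, so that differences well under 2-fold passed the test.

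**Figure D1:**
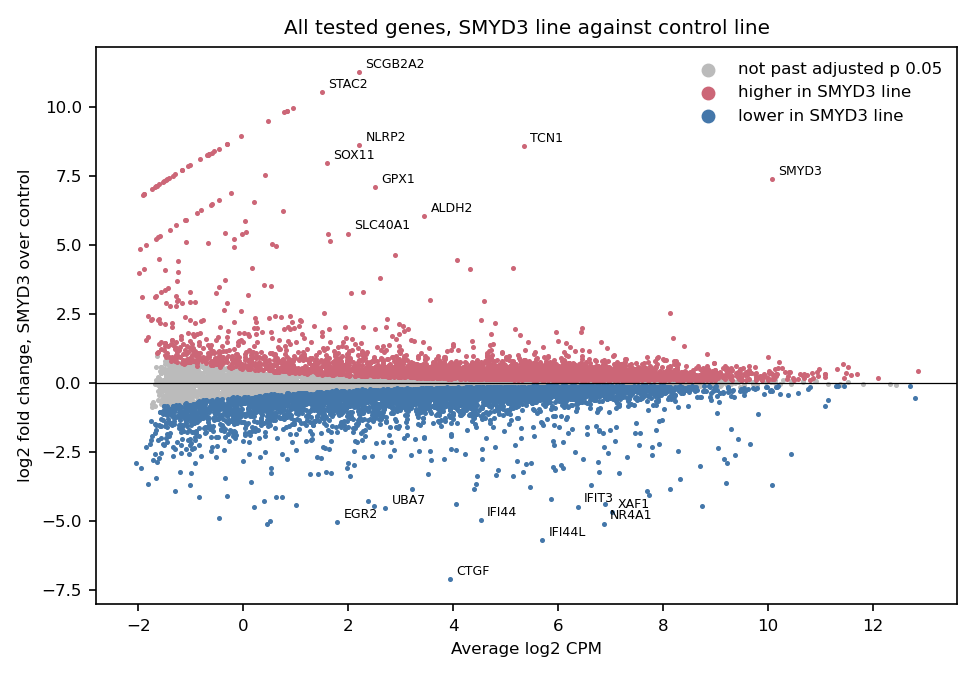
log2 fold change of SMYD3 over control cells against average log2 CPM for the 15226 tested genes, 1 point per gene, with SMYD3 and the 8 highest and 8 lowest characterised genes of a mean log2 CPM of at least 1 named. Genes with 0 counts in control cells, such as SCGB2A2 and STAC2, lie on lines at the upper left because their fitted fold change depends on the prior count and is not a bound.

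Interferon-stimulated genes fell together: 37 of 37 tested members were lower and 0 higher, and the same 37 were lower when adjusted over the list alone. Their median log2 fold change was -2.89. ISG15, a ubiquitin-like modifier, went from 1089 ± 28.1 to 88.7 ± 4.47 CPM (SD, n = 3), and OAS2, an antiviral synthetase, from 525.9 ± 10.5 to 36.3 ± 0.683 CPM. Of the MHC class I and antigen processing genes, 17 of 17 were lower (17 adjusted over the list alone), with a median of -1.82. HLA-B fell by 3.48 on the log2 scale, HLA-A by 2.62, and the immunoproteasome subunit genes PSMB8 and PSMB9 changed by -2.99 and -3.38. HLA genes are near-identical paralogs whose reads could be divided between them. Among NF-kappaB and inflammatory genes, 18 of 21 were lower and 1 higher, also when adjusted over the list alone, with a median of -1.16. The chemokine genes CCL5 and CXCL8 fell by 4.29 and 2.70 on the log2 scale, and LCN2 by 1.99.

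The preset-correlation camera test called all 3 of these lists lower, with adjusted p of 3.93e-306, 5.96e-74 and 2.85e-07. With an estimated correlation the interferon list was again called (adjusted p = 0.0155), whereas the antigen and NF-kappaB lists were not (adjusted p = 0.142 with an estimated correlation for each). Over the 30 tested lists the preset test called 11, of which the interferon list alone held with an estimated correlation. The preset test also called between 4 and 12 lists in the 9 splits of the 6 libraries that mixed the groups. In those splits edgeR called 0 genes (36 to 164 at an unadjusted p under 0.05). Each mixed split kept part of the group difference and put the rest into the spread between libraries. Its counts therefore do not show what happens without a group difference. With an estimated correlation 10 of the 11 calls were lost, at estimated values from 0.017 (NRF2 antioxidant genes) to 0.526 (ribosomal protein genes). The NRF2 value lies near the preset one, yet the adjusted p of that list rose from 6.10e-05 to 0.142. A higher correlation is therefore unlikely to be the only reason for the loss there. The loss does not by itself measure how weak a list call is. Because the calls depend on the form of the test, the member counts carry the description. The member counts are to be read beside all 15226 tested genes, of which 4659 were higher and 4713 lower.

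**Figure D2:**
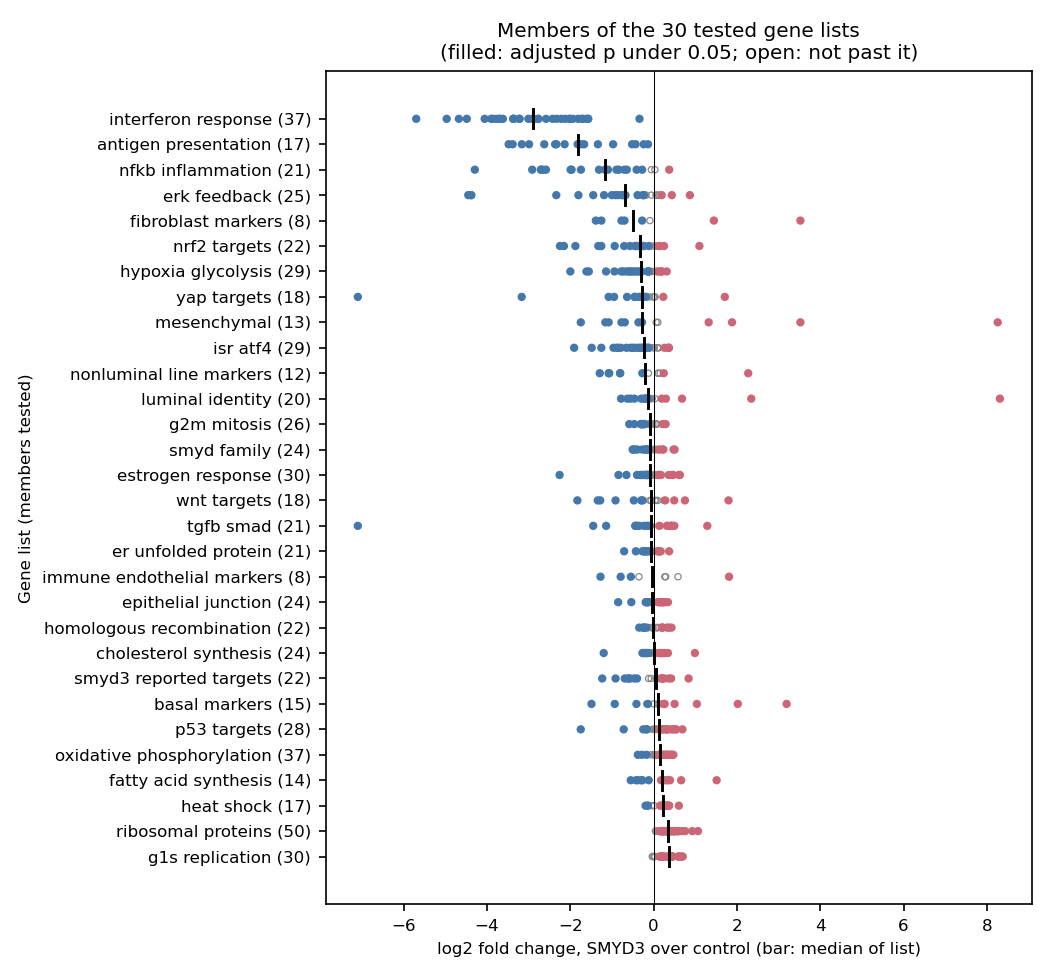
log2 fold change of each tested member of the 30 gene lists, ordered by list median (black bar), with the number of members tested in brackets. Filled points passed an adjusted p of 0.05 (blue lower, red higher in SMYD3 cells) and open points did not. All 37 interferon-stimulated and all 17 antigen presentation genes lie below 0, and 47 of 50 ribosomal protein genes are filled above it.

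Transcripts induced by ERK signalling were lower in 16 of 25 members and higher in 3 (the same numbers adjusted over the list alone), with a median log2 fold change of -0.67. EGR1 went from 820.4 ± 57.98 to 37.6 ± 0.902 CPM (SD, n = 3) and FOS from 226.3 ± 3.73 to 10.8 ± 0.756 CPM. FOSB and IER2 changed by -4.37 and -2.33 on the log2 scale. YAP and TAZ targets were lower in 12 of 18 and higher in 2 (also adjusted over the list alone), with a median of -0.28. CYR61 fell by 3.16, IGFBP3 by 0.95 and AMOTL2 by 0.63 on the log2 scale. Both lists were called lower by the preset camera test (adjusted p 3.38e-23 and 1.65e-05), but not with an estimated correlation (adjusted p = 0.142 and 0.184 with an estimated correlation). TGF-beta and SMAD response genes went both ways, 9 of 21 higher and 10 lower (10 and 10 adjusted over the list alone), with a median of -0.07 and a camera adjusted p of 0.39. In that list PMEPA1 rose by 1.29 and JUNB and LTBP2 fell by 1.45 and 1.14 on the log2 scale. Wnt targets were higher in 4 of 18 and lower in 7 (also adjusted over the list alone), with a median of -0.07 and a camera adjusted p of 0.408. AXIN2 and NKD2 fell by 1.34 and 1.28, while RNF43 rose by 0.75.

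Hypoxia-induced and glycolysis genes were lower in 20 of 29 members and higher in 5 (20 and 6 adjusted over the list alone), with a median of -0.31. NDRG1 went from 97.1 ± 4.40 to 31.8 ± 0.745 CPM (SD, n = 3), and ADM, PFKFB4 and ENO2 fell by 2.00, 1.14 and 0.94 on the log2 scale. NRF2 antioxidant genes were lower in 14 of 22 and higher in 4 (also adjusted over the list alone), with a median of -0.32. The aldo-keto reductase genes AKR1C2, AKR1C1 and AKR1C3 fell by 2.25, 2.15 and 1.88; they are near-identical copies, so the division of reads among them is uncertain. SLC7A11, a cystine transporter gene, was 2.38-fold lower. Integrated stress response genes were lower in 18 of 29 and higher in 4 (19 and 4 adjusted over the list alone), with a median of -0.24, and CBS, ALDH1L2 and ATF3 fell by 0.96, 1.48 and 1.91. Camera adjusted p values for these lists were 6.99e-05, 6.10e-05 and 0.000429. None of them held with an estimated correlation (adjusted p = 0.234, 0.142 and 0.222 with an estimated correlation). Genes of the endoplasmic reticulum unfolded protein response were mixed, 6 of 21 higher and 9 lower (also adjusted over the list alone), with a median of -0.06 and a camera adjusted p of 0.655. There SEC24D fell by 0.71 and HSP90B1 by 0.43, and CRELD2 rose by 0.37.

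G1/S and DNA replication genes were higher in 26 of 30 members and lower in 0 (also adjusted over the list alone), with a median log2 fold change of 0.37. RRM2, a ribonucleotide reductase subunit gene, went from 229.5 ± 4.84 to 366.0 ± 8.07 CPM (SD, n = 3), and UNG, DHFR and GINS2 rose by 0.70, 0.63 and 0.61. Cytosolic ribosomal protein genes were higher in 47 of 50 and lower in 0 (48 and 0 adjusted over the list alone), with a median of 0.34. RPLP0 and RPSA rose by 0.68 and 0.76, and RPL23 and RPL19, which neighbour ERBB2, by 1.07 and 0.93. These genes have many processed pseudogenes that could take or give reads. Their excess over control was 1.38 times as large in SMYD3 replicate 2 as in the mean of replicates 1 and 3 (95% bootstrap interval 1.28 to 1.44). Here and below, the bootstrap resampled the genes of a set, so its interval does not measure the spread between libraries. Cytosolic chaperone genes were higher in 12 of 17 and lower in 3 (also adjusted over the list alone), with a median of 0.22, and FKBP4 and HSP90AB1 rose by 0.61 and 0.32. The 3 lists were called higher by the preset camera test (adjusted p 1.59e-06, 1.46e-10 and 0.0405), but not with an estimated correlation (adjusted p = 0.142, 0.349 and 0.545 with an estimated correlation). The chaperone call was also lost without control replicate 2 (camera adjusted p 0.0508), SMYD3 replicate 1 (0.0654) or SMYD3 replicate 2 (0.0585), and with the replicate block (0.0599), the stricter filter (0.103), upper-quartile factors (0.0521) or GC and length offsets (0.119), within a range of 0.0103 to 0.119 over 15 settings.

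Nuclear genes of the respiratory chain were higher in 21 of 37 members and lower in 3 (24 and 3 adjusted over the list alone), with a median of 0.15 and a camera adjusted p of 0.06. NDUFA2 and SDHC rose by 0.45 and 0.41, and UQCRC2 fell by 0.38. The list was called without control replicate 3 (camera adjusted p 0.0492) or SMYD3 replicate 3 (0.0111), with no filter on low counts (0.0172) and without the ERBB2 stretch and near-absent genes (0.0439), within a range of 0.0111 to 0.597 over 15 settings, and its excess in SMYD3 replicate 2 was 1.43 times (95% bootstrap interval 1.27 to 1.65) that of replicates 1 and 3. G2/M and mitosis genes were higher in 2 of 26 and lower in 10 (also adjusted over the list alone), with a median of -0.09 and a camera adjusted p of 0.447. MKI67, a proliferation marker, fell by 0.25 on the log2 scale, CENPE by 0.58 and CENPF by 0.46. Homologous recombination genes were higher in 6 of 22 and lower in 5 (also adjusted over the list alone). Their median of -0.02 lay below 0 while their mean of 0.02 and the camera direction lay above it (adjusted p 0.729). RAD51 rose by 0.43 and RAD54L fell by 0.34. Targets of p53 were higher in 14 of 28 and lower in 5 (also adjusted over the list alone), with a median of 0.13 and a camera adjusted p of 0.386. CDKN1A, a cyclin-dependent kinase inhibitor gene, rose by 0.53, whereas GDF15 fell by 1.75.

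Oestrogen receptor targets were higher in 8 of 30 members and lower in 14, also when adjusted over the list alone, with a median of -0.07 and a camera adjusted p of 0.296. TFF1 rose by 0.36 (SE 0.06) and PGR, the progesterone receptor gene, by 0.17 (SE 0.05), while GREB1 fell by 0.40 and EGR3 by 2.25 on the log2 scale. ESR1, which encodes the oestrogen receptor, stood at 505.3 ± 9.09 CPM in control and 453.3 ± 26.4 CPM in SMYD3 cells (SD, n = 3), a log2 fold change of -0.16 with an adjusted p of 0.00613 (edgeR quasi-likelihood, Benjamini-Hochberg). Without SMYD3 replicate 2 the ESR1 change was -0.11 and no longer passed (adjusted p 0.0534, the highest of 16 settings, whose lowest was 0.00027; edgeR quasi-likelihood except for the DESeq2 and limma settings). Luminal identity genes were higher in 5 of 20 and lower in 11 (also adjusted over the list alone), with a median of -0.14 and a camera adjusted p of 0.439. Their mean of 0.40 had the other sign because of ANKRD30A, with 0 counts in control and 118 in SMYD3 cells, at least 39.9-fold higher. The median was again -0.14 with ANKRD30A at that bound. The keratin genes KRT8 and KRT18, which have many pseudogenes, fell by 0.55 and 0.63, GATA3 fell by 0.29, ELF3 by 0.78, and AGR2 rose by 0.68.

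Basal markers were higher in 6 of 15 members and lower in 4 (also adjusted over the list alone), with a median of 0.11 and a camera adjusted p of 0.535. TAGLN and ANXA1 rose by 2.02 and 3.19, and KRT17 fell by 1.49. Mesenchymal genes were higher in 4 of 13 and lower in 7 (also adjusted over the list alone). Their median of -0.28 had the other sign from their mean of 0.70 and from the camera direction (adjusted p 0.991). TWIST1 had 0 counts in control and 114 in SMYD3 cells, at least 38.5-fold higher, and the median was -0.28 with TWIST1 at that bound. The raised member COL1A2 rested on SMYD3 replicate 2. TNC rose by 1.88 and ITGA5 and LOX fell by 1.16 and 1.75, and VIM had a log2 fold change of 0.10 that did not pass (adjusted p 0.278, edgeR quasi-likelihood, Benjamini-Hochberg). Epithelial junction genes were higher in 9 of 24 and lower in 7 (also adjusted over the list alone), with a median of -0.04 and a camera adjusted p of 0.82. CDH1, which encodes E-cadherin, rose by 0.15, and PRSS8 and TJP3 fell by 0.85 and 0.53.

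Reported transcriptional targets of SMYD3 were higher in 7 of 22 members and lower in 8, also when adjusted over the list alone. Their median of 0.06 had the other sign from their mean of -0.12 and from the camera direction (adjusted p 0.617). MYC fell by 0.91, MET by 0.56 and PIK3CD by 1.23 on the log2 scale, and CCND1, which encodes cyclin D1, had a log2 fold change of 0.06 that did not pass (adjusted p 0.208, edgeR quasi-likelihood, Benjamini-Hochberg). Other SMYD and histone lysine methyltransferase genes were higher in 5 of 24 and lower in 9 (also adjusted over the list alone), with a median of -0.08 and a camera adjusted p of 0.729. SETD7 rose by 0.51, and EZH1 and SETDB1 fell by 0.50 and 0.44. Cholesterol biosynthesis genes were higher in 8 of 24 and lower in 7 (8 and 8 adjusted over the list alone), with a median of 0.003 and a camera adjusted p of 0.729. PMVK rose by 0.99 and STARD4 was 2.29-fold lower. Fatty acid synthesis genes were higher in 8 of 14 and lower in 6 (also adjusted over the list alone), with a median of 0.21 and a camera adjusted p of 0.408. FADS2 and ACACA rose by 1.51 and 0.66, while ELOVL6 fell by 0.55. ACACA lies in the raised stretch around ERBB2 described below.

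Markers of cells other than luminal epithelium were not called as groups by the preset camera test. Fibroblast markers were higher in 2 of 8 members and lower in 5 (also adjusted over the list alone), with a median of -0.49, a mean of 0.06 and a camera adjusted p of 0.256 in the lower direction. MGP rose by 1.45, and COL6A1 and COL6A2 were 2.61-fold and 2.38-fold lower. The other raised member, COL1A2, rested on SMYD3 replicate 2, with 12, 248 and 1 counts in SMYD3 replicates 1, 2 and 3. Leukocyte and endothelial markers were higher in 1 of 8 and lower in 3 (also adjusted over the list alone), with a median of -0.04, a mean of 0.001 and a camera adjusted p of 0.868 in the lower direction. VWF rose by 1.81 and CD8A fell by 0.79. Markers of non-luminal lines were higher in 2 of 12 and lower in 6 (also adjusted over the list alone), with a median of -0.20 and a camera adjusted p of 0.729. HOXB13 rose by 2.27, and SALL2 and CD44 fell by 0.80 and 0.27.

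**Figure D3:**
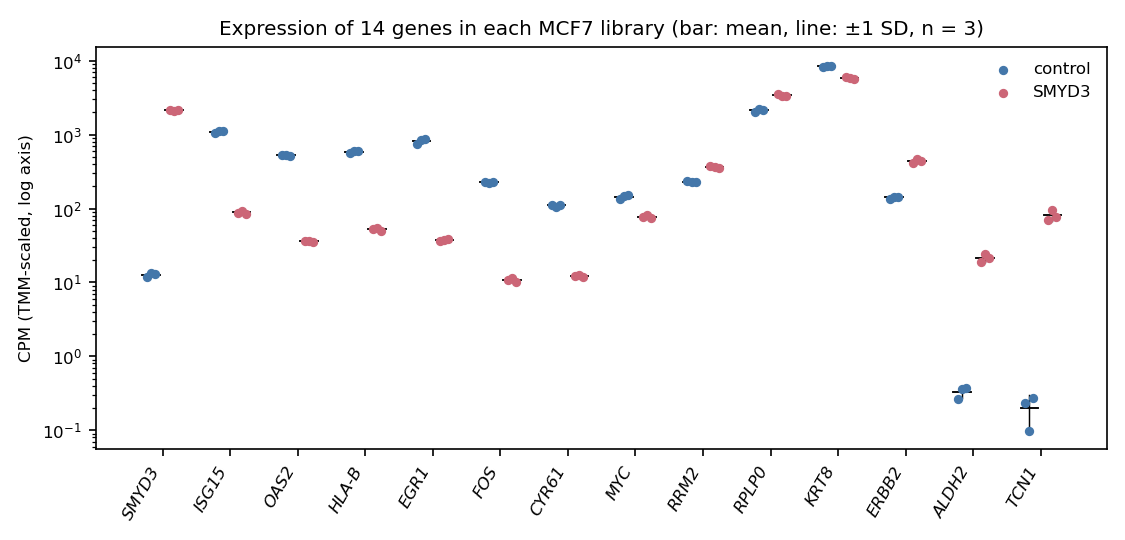
TMM-scaled CPM (log axis) of 14 genes in each of the 3 control (blue) and 3 SMYD3 (red) libraries, with the mean (bar) and 1 SD to either side (line). SMYD3 stands at 12.8 and 2142 CPM, and each gene shown has its groups apart.

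A scan of the tested genes in chromosomal order, chosen after the data were examined, found a stretch of 60 neighbouring genes around ERBB2, a receptor tyrosine kinase gene, in which 46 were higher and 7 lower. ERBB2 itself went from 141.6 to 440.8 CPM, a log2 fold change of 1.64 (SE 0.05, n = 3 per group). Its neighbour PGAP3 went from 10.2 to 45.7 CPM, FBXL20, LASP1, STARD3 and GRB7 rose by 1.52, 1.34, 1.30 and 0.99 on the log2 scale, and IKZF3 rose by 3.82. The highest running median of 21 genes was 1.07 and lay at RPL23, and 0 of 1000 shuffles of gene order gave one as high. Another 4 stretches were lower. PRSS16 to PRR3 and CFB to VPS52, which flank and hold HLA genes, had lowest running medians of -0.657 and -0.537. PRIM1 to CYP27B1 reached -0.597, with 15 of 26 genes lower and 1 higher. RPL36A to MORF4L2-AS1 reached -0.457, close to the bound of -0.455 from the shuffles. By a rule also set after the data were examined, 43 genes lay under 1 CPM in every control library and averaged at least 2 CPM in SMYD3 cells, among them LDHB, a lactate dehydrogenase gene, with 0 and 379 counts (at least 128.0-fold higher). By the mirrored rule 36 genes, among them CTGF, TRIM22 and CCL5, lay under 1 CPM in every SMYD3 library. The excess of the 43 genes near absent from control cells was 1.22 times (95% bootstrap interval 1.10 to 1.26) as large in SMYD3 replicate 2 as in replicates 1 and 3, and that of the raised genes near ERBB2 1.26 times (1.18 to 1.33). For 2572 other genes raised by a log2 fold change above 0.3 it was 1.09 times (1.08 to 1.10). That interval overlaps that of the 43 genes only at its edge and lies below that of the genes near ERBB2. These intervals cover the spread between genes and not between libraries.

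**Figure D4:**
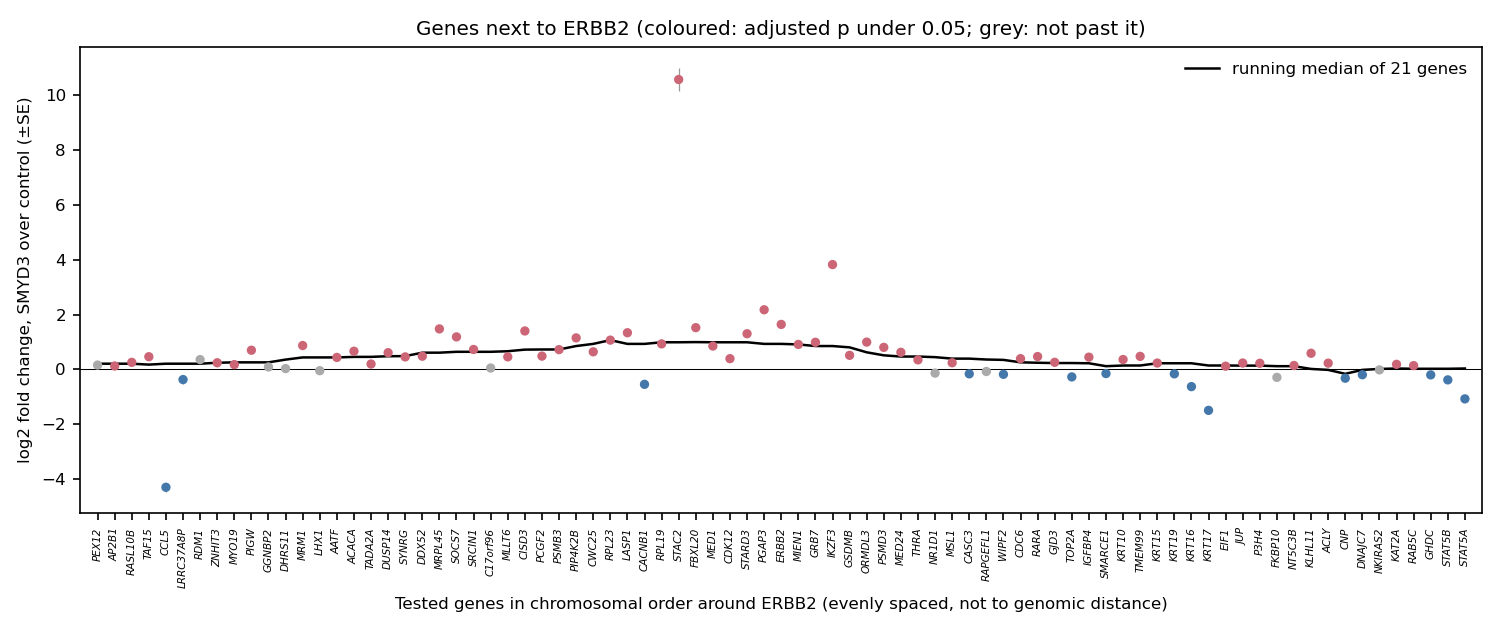
log2 fold change (point) with SE (line) of tested genes on either side of ERBB2, evenly spaced in chromosomal order, with the running median of 21 genes (black line). Red and blue points passed an adjusted p of 0.05 as higher and lower in SMYD3 cells and grey points did not, and the running median peaks at 1.07 at RPL23.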

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

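The GC and length offsets, the fit without the ERBB2 stretch and near-absent genes, and the upper-quartile, library-total and limma settings for lists were chosen after seeing the data. SMYD3 was called higher in all 16 other settings, with log2 fold changes from 7.30 to 7.43. The count of changed genes was 9372 and ranged from 6494 with the stricter filter, which tested fewer genes, to 10081 with GC and length offsets; leaving out a library gave 8288 to 9262. Asking for a log2 fold change of at least 1 left 1154 genes by construction. Other scalings moved the higher share between 44.4% and 50.4%, from 49.7%. Under the GC and length offsets 5 called genes were called in the other direction, none of them named here. Of 2184 values of 139 named genes, 2183 kept their direction and call, and the exception was ESR1 without SMYD3 replicate 2. Most of these genes were named for a small p or an extreme change in the same data, so few calls could be lost. Of all 9372 called genes, 8108 (DESeq2) to 9308 (RLE factors) kept call and direction, the stricter filter aside. That filter tested 6563 of them and kept 6133. The 11 called lists became 1 with an estimated correlation and 25 with fry, which asks another question and compares no list with other genes; the cause of the first was not tested. Leaving out a library gave 10 to 12 lists, with changes only in the chaperone and respiratory chain lists. The replicate block gave 9015 genes and 10 lists, without the chaperone list. Same-numbered libraries did not deviate together (correlations across genes -0.127 to -0.0616). This gives no sign of a pairing by number, but correlations over all genes cannot exclude one. Depth limits low genes most: 3 counts equal 0.0724 to 0.103 CPM.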

Other observations

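The splits of the libraries and the tests of the subtype markers, of handling at harvest and of ERK output were written down before their results were seen, and the other tests here were chosen after.

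Immediate early genes, written as a list of their own after the first results, were lower in 21 of 24 members and higher in 2. EGR1, FOS, FOSB, IER2, EGR3, CYR61, JUNB and ATF3, given above under ERK, oestrogen, YAP, TGF-beta or stress lists, are also members. Their falls under those lists are therefore not separate observations. Their median log2 fold change was -1.74, and their share of all counts went from 0.356% ± 0.0127 in control to 0.0758% ± 0.00172 in SMYD3 cells (SD, n = 3). JUN, IER3 and ZFP36 fell by 2.62, 1.80 and 1.67 on the log2 scale, while BTG2 and KLF2 rose by 0.54 and 0.46. Of 24 interferon genes, receptors, sensors and signalling factors chosen after the data were examined, 7 of them also in the interferon-stimulated list, 16 were lower, 3 higher and 5 not called. IFNL1 had 244 counts in control and 12 in SMYD3 libraries, IFNB1 66 and 11, and TLR3 113 and 17. STAT1, STAT2, IRF9 and DDX58 fell by 2.01, 1.61, 1.72 and 2.76 on the log2 scale. MAVS, JAK1 and IFNAR1 rose by 0.51, 0.26 and 0.22, and IRF3, IFNAR2, IFNGR1, IFNGR2 and the DNA sensor gene MB21D1 were not called.

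Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many changed genes as the real groups (9372; highest other 0) and 2 gave as many called lists (11; highest other 12). With 10 splits no share under 0.05 can be reached. The other splits mixed the groups, so part of the group difference fell into their spread. They are therefore no measure of libraries without a difference.

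Beside the 43 genes near absent from control cells and the raised stretch around ERBB2, 36 genes were near absent from SMYD3 cells, which RNA added by other cells would not by itself bring about. A trend with transcript length or GC content did not remove the higher level of the 43 genes in SMYD3 replicate 2 (median log2 ratio to replicates 1 and 3 of 0.297 after its removal, 0.279 before; matched random lists -0.0659 to 0.0562 after), nor that of the genes near ERBB2 (0.163 after, 0.166 before), while that of ribosomal protein genes fell from 0.0939 to 0.0460. A candidate explanation is RNA of a second cell population in the SMYD3 libraries. Both sets were higher in replicate 2 than in replicates 1 and 3 (0.279 and, for the excess near ERBB2, 0.333). The median ratio of replicate 3 to replicate 1 was 1.08 for the 43 genes and 1.01 for the excess near ERBB2. Ribosomal protein and respiratory chain genes deviated as much or more in their excess in replicate 2 (1.38 and 1.43 times, before any such removal). Their called members were raised by a median log2 fold change of only 0.34 and 0.19, so a small shift in level moves their excess much. In level, ribosomal protein genes deviated less (0.0939) than the 43 genes (0.279) and the genes near ERBB2 (0.166). These measures order the sets differently, so the excess of such lists does not decide on a second population. Markers of ERBB2-amplified or apocrine tumours were higher in 12 of 24 and lower in 6 (random lists 2 to 10 higher), and markers of non-luminal lines (packaging and mesenchymal-type cells) went both ways with a median of -0.20, so the kind of population stays open. A response to SMYD3 inside MCF7 cells remains possible too: SMYD3 itself had a log2 ratio of -0.0544 in replicate 2, but 3 libraries of a line cannot tell these apart, nor from a subclone that grew out during selection, which was not tested.

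The 1000 most abundant other control genes had a median log2 fold change of 0.0614 against -2.89 for the interferon-stimulated genes. Dilution by cells that lack those abundant genes therefore does not account for the fall of the list. Cells that share them but hold less interferon-stimulated RNA would leave that median near 0, so a part played by such cells stays open. Scaling does not account for the fall of the list either, since the median nearest to 0 under another scaling was -2.88. The list took 1.42% of control counts and 0.207% of SMYD3 counts. Whether SMYD3 lowered these genes or the control line held a raised interferon state, for example after infection, cannot be told apart with a line per group.

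The fall of the immediate early genes may reflect handling or signalling. Their spread within groups lay at percentile 71.2 of 10000 matched random lists, under the bound set beforehand for handling that varied from dish to dish. The labels do not say whether the libraries of a group were harvested separately. Only if they were does this value count against such handling. A difference in handling between the groups as a whole was not tested. Delayed ERK feedback genes had a median log2 fold change of -0.21, with 6 of 12 lower (DUSP4 and EPHA4 among them) and 2 higher (SPRY4 and ETV5). By the bound written beforehand, that median counts against a lower ERK output as a whole. The decision made here also allowed for the spread of the members, which that bound did not. With that allowance a lower ERK output as a whole stays open.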
